A study of Arabidopsis thaliana with 12 samples.

How the data were processed

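ChIP-seq of a tagged DELLA protein was done on inflorescences of 3 Arabidopsis genotypes, with 2 independent biological replicates per genotype per the labels. Each replicate used 1.8 g of tissue from plants grown at 22 °C with 16 h of light and 8 h of dark, and chromatin was sonicated for 9 cycles per the labels' protocols. There were 6 ChIP and 6 input libraries, in 6 groups. One peak list per ChIP library was analysed, so peaks were called per replicate and not on pooled replicates. Samples were grouped by the source names in the labels.

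The submitters' processing notes name cutadapt, Bowtie2, SAMtools, MACS2 and bedtools, with no versions, and the genome build TAIR10. Settings are not given in the sources used here. Each peak carries, as deposited, a score, a fold enrichment ratio and the −log10 of its p-value and q-value, in the layout of MACS2. The authors' score equals 10 times the −log10 q, truncated to a whole number, in every line of the 6 lists. The lowest −log10 q in each list lies just above 2. In the replicate 2 lists the decimal marks of the deposited fold and −log10 columns were damaged, and 5 decimals were restored, after which the same relation to the score holds in every line. All of these values are the authors', and they were used only to describe, rank or filter peaks within a list. The lists give no read counts, so depth is unknown and a longer list need not mean more binding. Intervals on shares of peaks or regions describe these lists and not the spread between plants.

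Overlap meant at least 1 bp. Reproducible regions were merged intervals that held a peak of both replicates and touched no Ler peak. The strength of a region was the mean, over its lists, of the within-list percentile of its highest peak by q-value. Overlap between replicates was compared with 1000 random placements on the same chromosomes. The genotype comparison used lists reduced to the length of the shortest, by q-value, and an exact permutation test over the 3 splits of the 4 tagged lists. Gene lists were tested with Fisher's exact test and Benjamini-Hochberg adjustment at 0.05. Wilson intervals are at 95%.

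Genes were named and assigned with a RefSeq table of assembly TAIR10.1, whose coordinates are not printed. All 446 genes of the 17 lists matched it by locus tag, 437 of them also by symbol. Because the table's assembly has another name than the files' build, its fit was checked: in 9 of the 10 outer chromosome arms, gai-YPet summits lay outside protein-coding genes more often as given (52.9% to 67.7% over the 10 arms) than after a shift of 5000 bp. The exception was the start of chromosome 2, with 60.0% against 61.7%. Gene assignment therefore rests on the assumption that nuclear positions are the same in both.

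Some plans changed once the files were seen. The table gives no strand, so the planned promoter windows were replaced by windows of 1000 bp to each side of a gene, and the promoter share by the share of regions beside genes. No genome sequence was used here, so the planned motif tests were not run. Organelle peaks were kept in counts of regions and left out of gene tests.

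Named genes followed a rule set before the data were examined: 11 genes of gibberellin signalling and the CUC family whatever their values, the 8 strongest genes in both genotypes, the 8 strongest in either genotype with no peak in the other, the 3 strongest control regions, and up to 4 bound members of each list by strength. Alternatives were a 50% reciprocal overlap, the stronger 50% of each list, lists of equal length, control peaks kept, each replicate list left out, pairing by replicate number, other gene windows, random lists matched on gene properties (10000 draws) and another background.

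The overlap and list tests were tested on simulated data. Overlap counts matched those of bedtools 2.31.1 in all 60 comparisons. A planted share of 60.9% shared peaks came back as 60.9%. Of overlap tests on 100 pairs of unrelated lists, 1% passed 0.05. These unrelated lists were placed by the same method as the test's random placements. Planted gene lists were called in 86.5% of 200 tests and unplanted ones in 0.0612% of 4900. Only the gibberellin and auxin lists, of 44 and 55 genes, were planted, so 86.5% does not cover shorter lists. Genes were drawn independently, so the 0.0612% does not cover neighbouring genes that share a region. It also includes tests of lost peaks, which can hardly pass. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.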

Results

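Chromatin immunoprecipitation followed by sequencing (ChIP-seq), with an antibody to GFP, was done on Arabidopsis inflorescences. The tagged protein was gai∆17-3xYPet, a GAI protein that lacks 17 residues and carries a yellow fluorescent tag, expressed from the GAI promoter. GAI is a DELLA protein, a nuclear repressor of gibberellin responses that gibberellin marks for degradation, and versions without the DELLA motif resist that degradation. CUC2 is a NAC transcription factor that sets organ boundaries in flowers and pistils. There were 3 genotypes, namely untagged Landsberg erecta (Ler), gai-YPet, and gai-YPet in the cuc2-1 mutant, with 2 independent biological replicates each and an input library for each ChIP library. The analysed data were 1 peak list per ChIP library, called for each replicate separately. Peak lists give no read totals, so the depth of each library is unknown.

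The lists differed in length. The Ler lists held 234 and 406 peaks. The gai-YPet lists held 7042 and 11289 peaks, and the gai-YPet cuc2-1 lists held 8193 and 3666. The median fold enrichment, the authors' own value for each peak, was 1.52 and 1.83 in Ler, 3.25 and 2.57 in gai-YPet, and 2.70 and 2.62 in gai-YPet cuc2-1.

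Plants without the tag measured the background of the antibody and chromatin. A small share of tagged peaks lay on it, which the short Ler lists limit. In the gai-YPet lists 225 (3.20%) and 83 (0.735%) peaks touched a Ler peak, and in the gai-YPet cuc2-1 lists 84 (1.03%) and 141 (3.85%). Counted the other way, 161 of the 234 peaks of Ler replicate 1 (68.8%) overlapped gai-YPet replicate 1, and 150 (64.1%) gai-YPet cuc2-1 replicate 2. With gai-YPet replicate 2 and gai-YPet cuc2-1 replicate 1 the shares were 31.6% and 30.8%. For Ler replicate 2 they ranged from 4.43% to 38.4%. Over all 30190 tagged peaks the share was 1.77%, against 0.746% when the Ler peaks were placed at random on their chromosomes (permutation of positions, one-sided p = 0.001, the smallest that 1000 placements can give). The share was 0.904% without Ler replicate 2, 0.845% with a reciprocal overlap of 50% and 0.503% with the stronger 50% of each list. The Ler replicates shared 51 regions. Of the 3 strongest, 2 lay on chromosome 4, from 3972694 to 3973452 and from 3977521 to 3978197, and the other on chromosome 5, from 11706339 to 11706583. Their nearest genes were the pseudogenes AT4G06708, AT4G06710 and AT5G31770, and their folds in replicate 1 were 1.48, 1.37 and 1.44. Regions that touched a Ler peak were left out of the counts of regions and bound genes that follow.

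In gai-YPet inflorescences, genes of gibberellin and other hormone pathways lay beside some of the strongest regions of the tagged DELLA protein. The region between SCL3, a GRAS protein that promotes gibberellin responses, and DWF5, a sterol reductase of brassinosteroid synthesis, lay on chromosome 1 from 18679430 to 18681799 (build TAIR10), with folds of 15.5 and 8.46 in replicates 1 and 2. Beside IAMT1, which methylates auxin, the folds were 12.9 and 9.31 (chromosome 5, 22410191 to 22411479), and beside DREB1A, a regulator of cold responses, 11.1 and 9.25 (chromosome 4, 13017440 to 13019657). The replicate lists overlapped more than random placement gave, and the share depended on the list counted. After removal of control peaks, 94.2% of the 6817 peaks of the shorter list overlapped the longer list, against 8.86% by random placement (permutation of positions, one-sided p = 0.001, the smallest that 1000 placements can give). With a reciprocal overlap of 50% the share was 54.4%. Of the 11289 peaks of the longer list, control peaks kept, 5836 (51.7%) overlapped the shorter list. Without regions on control peaks, 5770 regions were found in both replicates.

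The other genes among the 8 strongest in both genotypes were AT4G04630 (folds of 15.2 and 9.48 in gai-YPet), AT4G19380 (14.0 and 9.06), AT4G27240 (13.6 and 8.58) and CSLA01, a cellulose synthase-like gene (11.2 and 7.31). Regions lay mostly outside genes. Of 5755 nuclear gai-YPet regions, 42.3% had their summit outside every protein-coding gene but within 1000 bp of one, against 20.4% of random positions (permutation of positions, two-sided p = 0.002, the smallest that 1000 placements can give), and 33.1% had it inside a gene, against 54.2% of random positions. In gai-YPet cuc2-1 the share beside genes was 42.9% of 3187 regions, against 20.4% (permutation of positions, two-sided p = 0.002, again the smallest possible). The gene table gives no strand, so upstream and downstream sides were not separated.

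A gene was counted as bound where a region's summit lay in it or within 1000 bp of it in the TAIR10.1 gene table, so that 1 region can count for neighbouring genes. The tests of gene lists treat genes as independent and do not correct for such sharing. By this rule 4948 of 27444 nuclear protein-coding genes (18.0%) were bound in gai-YPet. Of the 17 gene lists fixed before the data were examined, 10 were bound more often than other genes (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over 34 list-and-genotype tests).

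Gibberellin genes were among the most often bound, with 28 of 44 (63.6%, Fisher's exact test, adjusted p = 3.12e-10). SCL3 was the strongest, followed by the transcription factors IDD9 (folds of 11.5 and 7.81) and IDD5 (10.0 and 8.41). GID1B, a gibberellin receptor, had folds of 9.38 and 7.28 on chromosome 3 from 23291234 to 23292859. Of the synthesis genes, GA20OX2 had 8.41 and 6.61 on chromosome 5 from 21054427 to 21055083, and GA3OX1 had 5.77 and 4.49 on chromosome 1 from 5346635 to 5347217. The receptor GID1C had folds of 3.01 and 3.22. GID1A, a receptor gene, and RGA, another DELLA gene, had no region. At GAI itself the folds were 1.74 and 1.78, and the transgene is built from GAI sequence, which the lists do not separate from the resident gene.

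Boundary, placenta and ovule genes were bound in 18 of 32 cases (56.3%, Fisher's exact test, adjusted p = 5.21e-06). The strongest were NGA3 (folds of 7.10 and 5.49), RPL (6.44 and 4.74), MP, an auxin response factor (4.47 and 4.90), and SHP2, a MADS-box gene of carpels and ovules (5.38 and 5.04). All 3 CUC genes were bound: CUC3 with 4.08 and 3.56 (chromosome 1, 28672633 to 28673492, inside the gene), CUC2 with 3.49 and 2.92 (chromosome 5, 21900838 to 21901171, outside the gene) and CUC1 with 3.13 and 2.71 (chromosome 3, 5109039 to 5109894, outside the gene). Floral and meristem genes were bound in 18 of 27 cases (66.7%, Fisher's exact test, adjusted p = 2.94e-07), led by CLV1, a receptor kinase of the shoot meristem (7.81 and 5.23), LFY, which specifies floral fate (7.72 and 6.14), PI, a floral organ identity gene (4.91 and 4.72), and KNAT1 (4.92 and 4.67).

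Genes of other hormones stood out as well. Auxin genes were bound in 34 of 55 cases (61.8%, Fisher's exact test, adjusted p = 2.38e-11), with TAR2, an auxin synthesis gene, at folds of 10.8 and 8.39, IAA4 at 9.20 and 8.46, PIN3, an auxin exporter, at 9.13 and 6.27, and IAA3 at 7.04 and 4.89. Jasmonate genes were bound in 16 of 23 cases (69.6%, Fisher's exact test, adjusted p = 4.65e-07), among them LOX2 (8.34 and 6.50), JAZ10 (7.33 and 5.92), MYB21 (7.66 and 5.96) and JAZ1 (6.60 and 5.34). Brassinosteroid genes were bound in 12 of 23 cases (52.2%, Fisher's exact test, adjusted p = 0.000492), with the co-receptor gene BAK1 at 11.4 and 7.15, BAS1 at 7.62 and 5.75, BKI1 at 6.99 and 5.95, and BEE2 at 6.03 and 5.73. Cytokinin genes were bound in 21 of 49 cases (42.9%, Fisher's exact test, adjusted p = 0.000136), with LOG8 at 9.67 and 5.68, ARR7 at 6.23 and 4.95, LOG3 at 6.18 and 5.34, and CKX5 at 5.62 and 3.78. Among genes of abscisic acid and ethylene, 10 of 30 were bound (33.3%, Fisher's exact test, adjusted p = 0.0804, and 0.000665 to 1 over 12 alternatives), EIL1 (8.14 and 6.65) and PYL5 (7.71 and 6.56) being the strongest.

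The remaining lists split. TCP transcription factors were bound in 16 of 24 cases (66.7%, Fisher's exact test, adjusted p = 9.94e-07), led by TCP7 (folds of 6.05 and 5.63) and TCP18 (7.03 and 5.84). Cell cycle genes were bound in 14 of 24 cases (58.3%, Fisher's exact test, adjusted p = 3.68e-05), led by KRP4, an inhibitor of cyclin-dependent kinases (10.4 and 8.41), and CYCD3;2 (8.29 and 5.74). Light signalling genes were bound in 10 of 21 cases (47.6%, Fisher's exact test, adjusted p = 0.00344), led by PIF6 (10.1 and 7.58) and PHYA (8.97 and 4.96). By Fisher's exact test, 5 of 17 clock genes (adjusted p = 0.301) and 7 of 23 photosynthesis genes (adjusted p = 0.248) did not differ detectably from other genes. The same held for lists of other cell types and tissues and for housekeeping genes, with 2 of 14 tapetum and pollen genes, 3 of 13 root genes, 1 of 14 seed storage genes and 2 of 13 housekeeping genes bound (Fisher's exact test, adjusted p = 1, 0.839, 0.615 and 1). Without gai-YPet replicate 1, 3 more lists passed, namely clock, photosynthesis, and abscisic acid and ethylene (Fisher's exact test, adjusted p = 0.000376, 2.07e-06 and 0.00822). With the 1000 bp to each side counted but not the gene itself, the cytokinin, light signalling and cell cycle lists did not pass (Fisher's exact test, adjusted p = 0.105, 0.0915 and 0.0609, each the highest of 12 alternatives, with lowest values of 6.63e-10, 1.68e-06 and 1.69e-08).

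**Figure D1:**
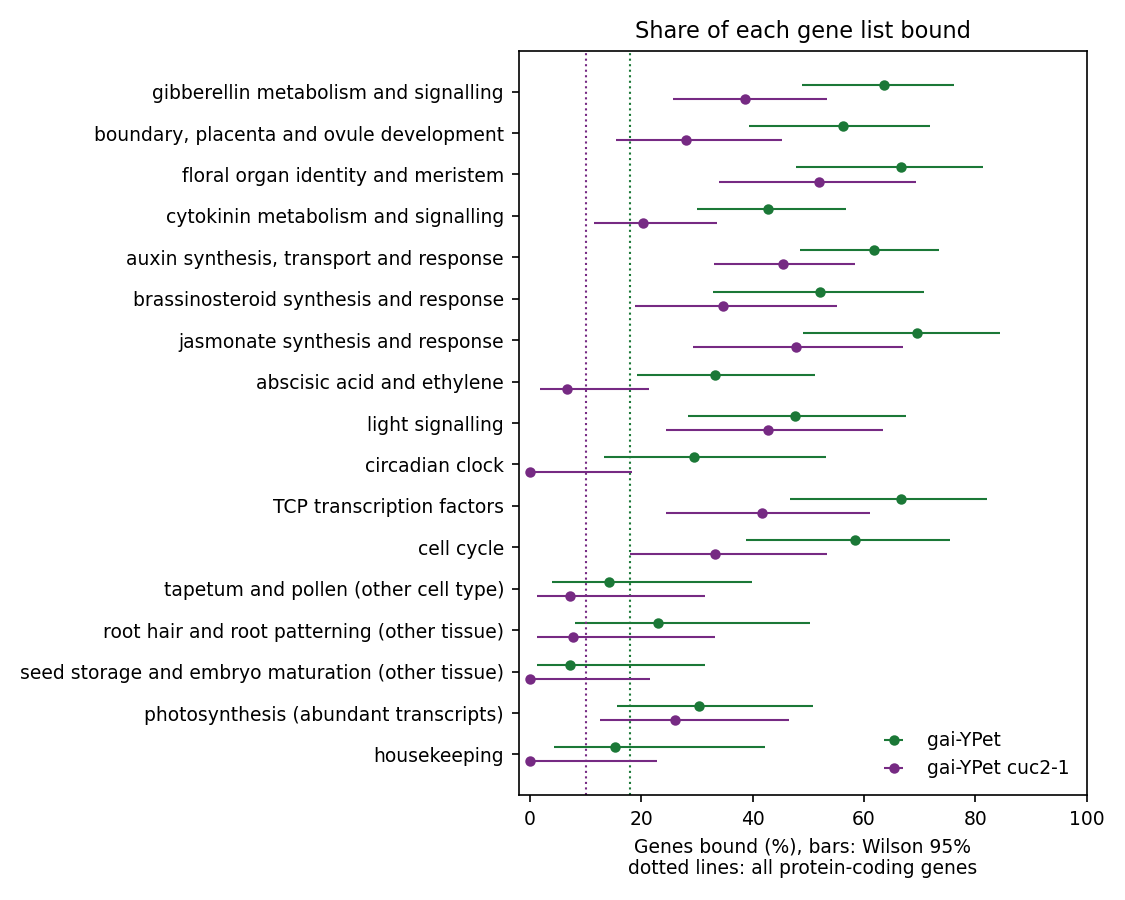
Share of each gene list that was bound (x axis, percent of genes) in gai-YPet (green) and gai-YPet cuc2-1 (purple), with points for the share, bars for its Wilson 95% interval, and dotted lines for all protein-coding genes (18.0% and 10.1%). Gibberellin genes reach 63.6% in gai-YPet and 38.6% in gai-YPet cuc2-1.

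The gai-YPet cuc2-1 plants address whether binding of the tagged protein depends on CUC2. All 577 regions of the strongest 10% in gai-YPet had peaks in both mutant lists. SCL3, DWF5 and IAMT1 were among the genes named for strong regions in both genotypes, so their mutant peaks follow from that choice. At the region between SCL3 and DWF5 the folds were 9.82 and 9.62, beside IAMT1 10.0 and 7.99, beside GID1B 6.85 and 4.27, and beside GA20OX2 7.67 and 5.86. CUC3 had folds of 3.02 and 2.35, whereas CUC1 (2.49), CUC2 (1.88) and GID1C (2.84) had a peak in replicate 1 only. CUC1, CUC2 and GID1C lay in the weaker 50% of gai-YPet regions. Mutant replicate 2 had a peak at only 15.8% of that weaker 50%, so its absence there is not particular to these genes. Replicate overlap was 95.8% of the 3525 peaks of the shorter list, against 6.27% by random placement (permutation of positions, one-sided p = 0.001, the smallest that 1000 placements can give), and 77.3% with a reciprocal overlap of 50%. Of the 8193 peaks of the longer list, control peaks kept, 3305 (40.3%) overlapped the shorter list. There were 3247 regions found in both replicates.

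By the same rule 2780 genes (10.1%) were bound in gai-YPet cuc2-1, and 11 of the 17 lists were bound more often than other genes. Auxin genes were bound in 25 of 55 cases, floral and meristem genes in 14 of 27 and gibberellin genes in 17 of 44 (Fisher's exact test, adjusted p = 3.12e-10, 4.4e-07 and 2.36e-06). Jasmonate genes followed with 11 of 23, TCP genes with 10 of 24 and light signalling genes with 9 of 21 (Fisher's exact test, adjusted p = 1.63e-05, 0.000151 and 0.000254). Brassinosteroid genes had 8 of 23, cell cycle genes 8 of 24, and boundary, placenta and ovule genes 9 of 32 (Fisher's exact test, adjusted p = 0.00283, 0.00344 and 0.0064). Photosynthesis with 6 of 23 and cytokinin with 10 of 49 were closest to the threshold (Fisher's exact test, adjusted p = 0.0406 and 0.0462). Of the photosynthesis genes, RBCS2B and RBCS1B were counted from the same region. The lists that did not pass were abscisic acid and ethylene with 2 of 30, tapetum and pollen with 1 of 14, root with 1 of 13, and clock, seed storage and housekeeping with 0 of 17, 0 of 14 and 0 of 13 (Fisher's exact test, adjusted p = 0.866, 1, 1, 0.532, 0.526 and 0.77; Wilson upper limits of the last 3 shares 18.4%, 21.5% and 22.8%). The photosynthesis and cytokinin lists did not pass in a permutation test with random lists matched on gene length (adjusted p = 0.0762 and 0.14, and 0.000116 to 0.548 and 6.74e-06 to 0.256 over 12 alternatives). With the gene itself left out, the photosynthesis and cytokinin lists did not pass either (Fisher's exact test, adjusted p = 0.137 and 0.256). Nor did the boundary, TCP and cell cycle lists (Fisher's exact test, adjusted p = 0.392, 0.0597 and 0.147, each the highest of 12 alternatives, with lowest values of 1.33e-06, 4.31e-06 and 1.37e-06). With 3000 bp to each side the tapetum and pollen list lay above other genes (Fisher's exact test, odds ratio 3.43, adjusted p = 0.0416).

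Most gai-YPet regions also had a peak in the mutant. Of the 5770 gai-YPet regions, 5211 (90.3%) overlapped a peak of at least 1 gai-YPet cuc2-1 list, and 559 (9.69%, Wilson 95% interval 8.95 to 10.5) overlapped none. The strongest genes without a mutant peak were UMAMIT2 (folds of 3.60 and 3.49 in gai-YPet), CIPK3, a kinase, with its neighbour FUS12 (3.40 and 4.09, chromosome 2, 11518128 to 11518995), PAO2, a polyamine oxidase (3.57 and 3.54), ZFHD1 (3.68 and 3.39), LACS1, an acyl-CoA synthetase of the cuticle (3.39 and 3.79), AT2G24360 (3.45 and 3.02) and LOH2, a ceramide synthase (3.71 and 2.83). These regions were weak in gai-YPet. Their median strength, the mean over replicates of a peak's percentile within its list, was 32.2 against 67.4 for regions with a mutant peak. The share without a mutant peak was 47.8% among the weakest 10% of regions and 0% among the strongest 10%. The mutant lists differed, with a peak at 5202 gai-YPet regions in replicate 1 and at 2884 in replicate 2. The share with no mutant peak was 50.02% without mutant replicate 1, 44.5% without gai-YPet replicate 1, and 4.42% with all tagged lists reduced to equal length.

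**Figure D2:**
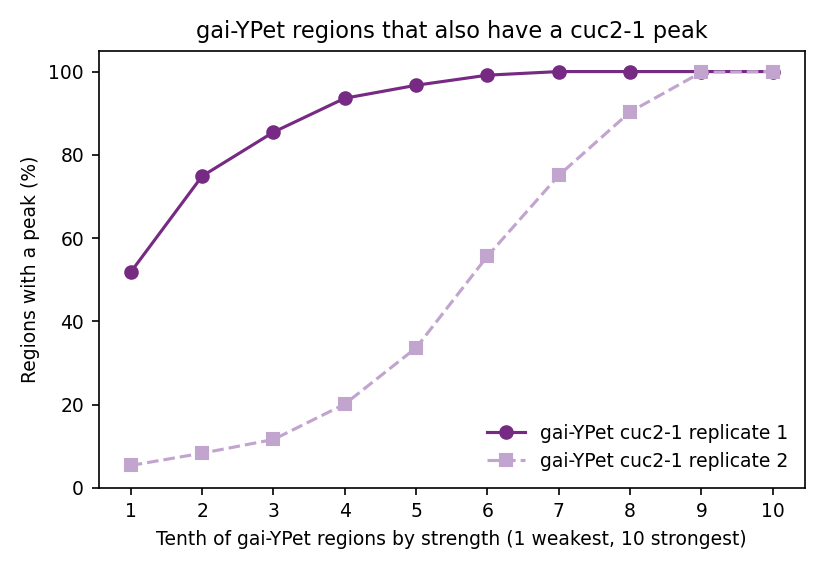
Share of gai-YPet regions with a peak in each gai-YPet cuc2-1 list (y axis, percent) by class of region strength (x axis, 10 classes of 577 regions, from 1, weakest, to 10, strongest), with circles for replicate 1 and squares for replicate 2. Replicate 1 goes from 51.8% to 100% and replicate 2 from 5.37% to 100%.

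Of 217 bound genes in the fixed lists, 15 had no mutant peak. Of all 4948 genes bound in gai-YPet, 409 (8.27%) had no mutant peak, and 0 of 17 lists differed from the rest after adjustment or at an unadjusted p under 0.05 (Fisher's exact test, lowest unadjusted p = 0.0576, for the clock list). These tests had little power, because the lists held few bound genes. Even 0 of 16 jasmonate genes gave an unadjusted p of 0.637 (Fisher's exact test), so differences between lists in lost peaks are not excluded. Among the 28 bound gibberellin genes, GAI and GA2OX6, a gibberellin-inactivating enzyme (folds of 2.40 and 2.11), had none. Of the 21 bound cytokinin genes, ARR16, CRF2 and CRF4 had none. The single members were FUL of 18 boundary and ovule genes, SEP2 of 18 floral genes, ARF17 of 34 auxin genes, CYCD4;1 of 14 cell cycle genes and RD29A of 10 genes of abscisic acid and ethylene. Of the 5 bound clock genes, PRR9 and LNK2 had none. ATA7, CPC and GAPC2 were the members without a mutant peak in the tapetum, root and housekeeping lists. The other lists had 0 such genes, among 12 bound genes for brassinosteroids, 16 for jasmonate, 10 for light signalling, 16 for TCP factors, 7 for photosynthesis and 1 for seed storage.

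In the other direction, 65 of the 3247 gai-YPet cuc2-1 regions (2.00%, Wilson 95% interval 1.57 to 2.54) had no gai-YPet peak. The share was 12.8% without gai-YPet cuc2-1 replicate 2, 4.34% without gai-YPet cuc2-1 replicate 1 and 3.39% without either gai-YPet list in turn, and 1.24% with all tagged lists reduced to equal length. These regions were weak, with a median strength of 14.3 against 65.4 for the rest. The 8 strongest genes were AT2G07718, AT2G07648, AT2G07719, AT2G07623, AT2G07631, AT2G07636, AT2G07692 and AT2G07698, all on chromosome 2. The first 3 shared a region from 3430525 to 3431704 with folds of 1.95 and 1.75. Of the 65 regions, 24 lay on the mitochondrial chromosome and 21 on chromosome 2 between 3200000 and 3700000, a window set after the data were seen, where a copy of the mitochondrial genome is inserted.

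The difference between genotypes was set against that between replicates with all 4 tagged lists at 3525 peaks. Mean overlap was 82.8% within genotypes and 80.0% between them, a difference of 2.80 percentage points (exact permutation test over 3 splits, p = 0.333, the smallest these splits allow). The gai-YPet replicates shared 88.8% and the gai-YPet cuc2-1 replicates 76.8%. Between genotypes, gai-YPet replicates 1 and 2 shared 86.7% and 82.8% with gai-YPet cuc2-1 replicate 1, and 76.3% and 74.2% with gai-YPet cuc2-1 replicate 2. With a reciprocal overlap of 50% the difference between genotypes was 1.69 percentage points (exact permutation test over 3 splits, p = 0.667). Another split of the lists then gave at least as large a difference. With 2 lists per genotype the test cannot reach 0.05, so a difference larger than that between replicates was not shown.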

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

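The tests in this part, of list order, of genotype and of the flanks of the insertion on chromosome 2, were chosen after the peaks were seen.

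Organelle peaks lie outside the nuclear genes that were tested, and are counted here in the full lists, with peaks on Ler peaks kept. All 4 tagged lists held more mitochondrial peaks than either control list, which held 0 and 4: gai-YPet had 126 and 20, and gai-YPet cuc2-1 had 303 and 81. The gai-YPet replicate 1 list held 80 chloroplast peaks, against 56 and 5 in the Ler lists. The other tagged lists held 32 in gai-YPet replicate 2, and 0 and 3 in gai-YPet cuc2-1, all below the 56 of Ler replicate 1. Control lists are far shorter, so a higher count is not by itself a higher enrichment. The median fold of mitochondrial peaks in gai-YPet cuc2-1 replicate 1 was 1.64, against 2.79 for peaks elsewhere in that list.

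For the mitochondrial peaks, a candidate explanation is mitochondrial DNA in some libraries with reads shared by its nuclear copy: 4 of 4 tagged lists had the same rank by mitochondrial and by insertion peaks, the latter being 86 and 16 in gai-YPet and 257 and 60 in gai-YPet cuc2-1. The Ler lists also held insertion peaks, 9 of 234 and 11 of 406 peaks, beside 0 and 4 mitochondrial peaks, so insertion peaks occurred without mitochondrial ones. Both Ler shares were higher than the 86 of 7042 and 16 of 11289 in gai-YPet and the 60 of 3666 in gai-YPet cuc2-1 replicate 2. The 257 of 8193 in gai-YPet cuc2-1 replicate 1 lay between the Ler shares. Pericentromeric chromatin around the insertion stays open: its flanks held 0.0621 times as many tagged peaks per Mb as the window, but the window was set with the peaks in view, which largely fixes that ratio. Mitochondrial and insertion regions made up 45 of the 65 regions seen only in cuc2-1 (69.2%, against 1.57% of shared regions). Loss of CUC2 stays open too, because the exact permutation test between genotypes gave p = 0.667 in a design of 2 lists against 2 that cannot go below 0.333.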

How the results depend on the processing

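Alternatives with nuclear chromosomes only, gene windows, matching on intergenic space or strength, the symbol background, control overlap with single control lists, and all those for the share beside genes were chosen after seeing the data; the others before. Control overlap, both replicate overlaps, both shares of regions beside genes and the genotype difference in overlap kept their direction and side of the threshold in the 33 alternatives run on them, though the last cannot pass it. Depth is unknown and limits every share.

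Counts of gai-YPet regions became 3710 with 50% reciprocal overlap, 3170 with the stronger 50% of each list and 2962 at equal length; cuc2-1 regions became 1691 with the stronger 50%. Leaving out each list gave 5771 to 11206 gai-YPet and 3259 to 8109 cuc2-1 regions, the high ends being single lists by construction (gai-YPet replicate 2 alone, cuc2-1 replicate 1 alone).

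The share of gai-YPet regions without a cuc2-1 peak was 18.6% with reciprocal overlap, 6.40% with the stronger 50%, 4.42% at equal length and 50.1% against reproducible cuc2-1 regions. Leaving out each list gave 9.66% to 50.02%, the highest without cuc2-1 replicate 1, and 44.5% without gai-YPet replicate 1. The opposite share was 3.53%, 0%, 1.24% and 4.59% in the same order, 1.29% on nuclear chromosomes only, and 1.99% to 12.8% leaving out each list, the highest without cuc2-1 replicate 2. The cause of these moves was not tested, beyond list length.

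Pairing lists by replicate number as a block gave 42.8% and 16.5% for these shares, as means over single lists. The numbers were not taken to pair the samples, since the labels name no shared batch; split by number, the overlap difference was -0.73 percentage points, which over 3 splits can show neither pairing nor its absence.

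Lists past the threshold numbered 8 to 13 in gai-YPet and 6 to 11 in cuc2-1, with 6 for flanks without the gene, and 0 for lost peaks throughout. The tests of lost peaks had little power, because the lists held few bound genes. The tapetum and pollen list in cuc2-1 turned from below to above other genes with 3000 bp to each side (odds ratio 3.43). Of the calls for single lists, 629 were the same, 19 no longer passed and 6 passed newly, and 4 odds ratios for lost peaks without cuc2-1 replicate 1 had no value. The motif alternatives were not run.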

Other observations

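The gene families and microRNA genes in this part, and all tests on them, were chosen after the data were seen, as were the tests of region strength, intergenic space and gene symbols. The test of pairs of lists and that of control peaks near list genes were set before their values were seen.

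Among 90 gene families defined by a shared symbol of at least 15 members, 5 were bound more often in gai-YPet than other named genes and 1 less often (Fisher's exact test, adjusted over families). SPL transcription factors, which promote the change to flowering, were bound in 11 of 16 cases (Fisher's exact test, adjusted p = 0.00307), and 11 of 16 were bound in cuc2-1. TCP genes were bound in 12 of 17, SAUR genes, small auxin-induced genes, in 10 of 16, TRM genes in 16 of 33 and genes named GA for gibberellin in 10 of 17 (Fisher's exact test, adjusted p = 0.00145, 0.0152, 0.0197 and 0.0197). Every bound TCP and GA member is also in the fixed TCP or gibberellin list, so these families largely repeat the tests given above. Genes named EMB for their embryo-defective mutants were bound in 6 of 112 (5.36%, against 22.7% of other named genes, Fisher's exact test, adjusted p = 9.47e-05). In a permutation test with random families matched on intergenic space, the adjusted p-values for SPL, TCP, SAUR, TRM and EMB were 0.018, 0.0216, 0.048, 0.0489 and 0.018, while the GA family did not pass (0.11). Both tests treat genes as independent, so neighbouring members that share a region count separately. How far bound members of a family, such as the SAUR genes, share regions was not tested.

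Of 326 microRNA genes, 42 (12.9%) were bound in gai-YPet, against 18.0% of nuclear protein-coding genes, a difference not tested. The rule for a bound gene covers more sequence at longer genes, and these shares were not matched on gene length. The strongest was MIR172b, whose product targets AP2-like genes, with folds of 9.70 and 7.61. MIR166a, from a family that targets HD-ZIP III genes, had 7.24 and 6.41, and MIR156c, from a family that targets SPL genes, had 4.62 and 4.64. MIR164b, from the family that targets CUC1 and CUC2, had 2.47 and 2.35. It was 1 of 3 bound microRNA genes without a cuc2-1 peak, with MIR161 and MIR166c.

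For the 559 gai-YPet regions without a cuc2-1 peak, peaks near the calling threshold are a candidate explanation: 0.139% of the stronger 50% of regions lacked a cuc2-1 peak. That value rests on cuc2-1 replicate 1, since in the shorter list of replicate 2 only 84.2% of these stronger regions had a peak. Loss of CUC2 stays open. For a test at equal length, each tagged list was cut to its 3525 strongest peaks after removal of control peaks. Of the regions shared by the cut gai-YPet lists, 4.17% were absent from both cut cuc2-1 lists. The 4.42% given above came from lists cut before that removal. However, 4.86% of the regions shared by the cut lists of gai-YPet replicate 2 and cuc2-1 replicate 1 were absent from the remaining cut lists. The Wilson intervals overlapped (3.50 to 4.97 and 4.14 to 5.71). The gai-YPet pair thus missed the excess set in advance for an effect of CUC2, and 2 lists per genotype keep the question open. A region absent from the cut lists can still have a weaker mutant peak. Of the 559 regions, 555 lay in the weaker 50%, and the cut removes weaker peaks, so this test says little about them.

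For the lists bound more often than other genes in gai-YPet, intergenic space and better studied genes were argued against as the whole cause. Matched on intergenic space, 10 lists still passed in gai-YPet, and against genes with a symbol of their own 10 lists passed. In gai-YPet cuc2-1, 9 lists passed in each case. The cytokinin and photosynthesis lists then did not pass when matched on space (permutation test with random lists, adjusted p = 0.154 and 0.0789). Nor did they against genes with a symbol (Fisher's exact test, adjusted p = 0.211 and 0.183), so for them in gai-YPet cuc2-1 both explanations stay open. With control peaks kept, 3 of 218 bound list genes (1.38%, Wilson 95% interval 0.469 to 3.97) had a control summit within reach. That met the rule set in advance against background of the antibody as the cause. The short Ler lists largely fixed this outcome, since only 67 of all 27444 protein-coding genes had a control summit within reach. The share among bound list genes was still the higher, a difference not tested. Background at some list genes therefore stays open, as does weak background that the short control lists would miss. Chromatin accessibility was not tested, nor was any biological explanation.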
